A study of Mus musculus with 6 samples.

How the data were processed

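Colonic mucosa of 8-week-old FVB/N6 mice was profiled in 6 pools of 5 mice each, 1 pool for each combination of genotype (WT or Foxo4_KO) and treatment (untreated, 50% ethanol enema, or TNBS in 50% ethanol, sampled on day 2). Per the labels, RNA was extracted with Trizol, cleaned on columns with DNase, and amplified to biotin-labelled cRNA for Illumina mouse bead arrays. The scanner and image software are not given in the sources used here. The numbers that the labels give to the samples count arrays, not replicates. A TNBS amount of 250 mg is labelled without the quantity it refers to.

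The deposited unnormalized table held, for each array, the mean bead signal of every probe as an intensity with no background subtraction. Beside each signal the deposited table held a detection score, which per the file headers is a p-value but rises with the signal (Spearman correlation over probes 0.997 to 0.998), so it was read as 1 minus p. The authors' second table held intensity values that were quantile normalized on the linear scale without background subtraction, as their common distribution shows, and it carried the probe identifiers. Both tables were joined by matching each unnormalized signal profile to the normalized profile of like rank on all 6 arrays, within a distance of 0.05 (log2) and with a second-best match at least 2 times as far. Of 46632 probes 46602 (99.94%) were joined. As a check, 7963 of 8038 targets with an Entrez number matched the probe's own number (99.1%), against 1 after shuffling, and on simulated data 99.99% were joined and 100% of these rightly.

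Signals were background corrected, quantile normalized and put on the log2 scale with neqc in limma 3.58.1 (R 4.3.3), with background inferred from detection p and an offset of 16. Probes with 1 gene symbol were kept where detection p was under 0.01 on at least 1 of the 6 arrays (11768 probes), and each of the 8951 genes was represented by its probe with the highest mean, 2217 genes having several. Probes with no symbol (16646) or several (10) were left out. Coordinates were not used here. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

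With 1 pool per group, limma was fitted with an additive model of treatment and genotype, in which the 3 treatments stand in for replicates of a genotype and both genotypes for replicates of a treatment. This left 2 residual degrees of freedom, which empirical Bayes moderation combined with 1.51 prior degrees of freedom (prior SD 0.0688, median residual SD 0.0838). Residuals hold genotype-by-treatment differences, so a gene whose response differs between genotypes is less readily called. Adjusted p-values are Benjamini-Hochberg values over all genes of a contrast, two-sided, with a threshold of 0.05. Contrasts were Foxo4_KO minus WT, ethanol minus untreated, TNBS minus ethanol and TNBS minus untreated. Single pools were compared by log2 difference alone, counting genes at least 2-fold apart (log2 of 1) that were detected on at least 1 of the arrays compared, and a gene below background in the lower pool is given as at least N-fold.

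The 40 gene lists of pathways and cell types were fixed before the data were examined, as were the contrasts, the settings, the alternatives and the rule for named genes, and 35 lists had at least 5 measured genes. Lists were tested with camera (preset inter-gene correlation 0.01) with adjustment over all lists of a contrast, then with an estimated correlation and with fry. For single pools a list's median was set against 10000 random lists of the same size matched on mean signal in 10 bins, as a description. The rule named the FoxO family, the 10 largest rises and falls past the threshold with 1 direction in every pair, up to 3 members of each list with the largest change, and the 10 highest and 10 lowest genes of each single-pool comparison of genotypes and of the response difference. Gene models without a gene name were skipped. Genes named outside this rule are said to be chosen after their values were seen.

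The additive model was tested on 20 simulated data sets with 200 changed genes of 8951, under 2 noise models. With variances drawn from the fitted prior, 78.5% of genes changed by 1 (log2) and 96.2% of those changed by 3 were recovered for genotype, with 5.34% false calls, and 68.7% and 94.8% for TNBS minus ethanol, with 4.8% false. With each gene's moderated SD, recovery for genotype was 92.3% and 99.2% with 4.82% false calls, and for TNBS minus ethanol 87.4% and 99.2% with 4.62% false. These recovery rates hold for 200 genes changed at once, which eases the adjusted threshold for each of them. On the arrays Rsad2, at 2.08 for genotype, had an adjusted p of 0.386 in limma. An absent call on the arrays therefore does not show that few genes differed. In the simulated data camera called 1 of 700 unchanged lists under the first noise model and 2 of 700 under the second. The simulated genes were drawn independently of one another, as the preset nearly assumes. On the arrays the estimated correlation was 0.484 in the interferon response, 0.874 in the neutrophil and −0.031 in the FoxO target list. These rates of false calls therefore do not carry over to lists of correlated genes. A list shifted by 1 was called in 20 of 20 data sets with the preset and in 0 of 20 with an estimated correlation.

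Alternatives chosen then were no background correction, the authors' normalized values, an offset of 50, no detection filter, detection on all 6 arrays, every probe kept apart, median scaling, a trended and robust prior, the covariate left out, each array left out in turn, an estimated correlation and fry. Alternatives without both TNBS pools, without both untreated pools, and without ileal and Paneth cell genes were added after seeing the data. No paired analysis was possible by label number, because each array has its own number and none is shared between groups, so pools were matched only by treatment and genotype, as in the additive model. The lowest detected log2 signal was 6.56 to 6.58, so values near it say little about fold.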

Results

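Gene expression in mouse colonic mucosa was measured on 6 Illumina bead arrays, each hybridised with RNA pooled from 5 mice. The pools formed 6 groups of 1 array each: wild-type (WT) and Foxo4 knockout (Foxo4_KO) mice that were left untreated, were given a 50% ethanol enema, or were given the hapten trinitrobenzenesulfonic acid (TNBS, labelled 250 mg) in 50% ethanol, with tissue taken on day 2 after the enemas. TNBS in ethanol is a common way to provoke colitis in mice, and ethanol alone is its vehicle. Mean signal per array was 236 in the untreated, 225 in the ethanol and 237 in the TNBS pool of WT mice, and 230, 227 and 277 in the corresponding Foxo4_KO pools. Probes detected above background numbered 13127, 11886 and 11181 in these WT pools and 11568, 12868 and 14363 in these Foxo4_KO pools. No group had replicates, so a difference between single pools is given as a value without a test, and the number of arrays limits the precision of every estimate.

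Foxo4 encodes a forkhead transcription factor that acts downstream of insulin and growth factor signalling. Its 1 probe was not above background on any array, with detection p between 0.168 in the untreated WT pool and 0.903 in the Foxo4_KO TNBS pool. Normalized log2 signal of Foxo4 was 6.52, 6.51 and 6.50 in the untreated, ethanol and TNBS pools of WT mice and 6.50, 6.52 and 6.46 in those of Foxo4_KO mice, so the arrays did not check the genotype labels. Whether the probe lies in the deleted part of the gene is not given in the sources used here. Of the related genes, Foxo1 was above background on all 6 arrays and differed between genotypes by 0.04 (log2, adjusted p = 0.859), and Foxo3 differed by 0.09 (adjusted p = 0.67).

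The first comparison asked which transcripts differ in Foxo4_KO mucosa across the 3 treatments. Interferon response genes stood higher in the Foxo4_KO pools: 20 of 23 measured members were higher in all 3 pairs of pools, and the median member was higher by 0.53 (log2). Rsad2, an antiviral enzyme, was higher by 2.08 (SE 0.164), Ifit2, an inhibitor of viral translation, by 1.81 (SE 0.103), and Oas2, a sensor of double-stranded RNA, by 1.40 (SE 0.229). Genes of MHC class II presentation went the same way, with 7 of 8 higher in every pair, among them the antigen-presenting chain H2-Ab1 (1.72, SE 0.202) and the invariant chain Cd74 (1.69, SE 0.29). Among leukocyte markers, higher values were those of Laptm5 of myeloid cells (1.36, SE 0.232), Cd3d of the T cell receptor (0.45, SE 0.066) and Mzb1 of plasma cells (1.01, SE 0.253).

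No gene passed an adjusted p of 0.05 in limma for genotype: the lowest adjusted p was 0.225, with 339 genes higher and 489 lower at an unadjusted p under 0.05. With a trended and robust variance prior limma called 4 genes, all higher, which were Rsad2, Ifit2, the secreted factor Nenf and the preadipocyte factor Dlk1. Genes at least 2-fold apart in all 3 pairs numbered 11 higher, including Nenf (2.48), the interferon-inducible Apol9a (1.99) and the GTPase Irgm2 (1.65). Another 2 were lower, Fxyd4, a regulator of the sodium pump (−2.19, SE 0.417), and Casp14, a protease of epithelial differentiation (−1.39, SE 0.135). Dlk1 and the group of genes at least 2-fold apart in all pairs were chosen after their values were seen.

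**Figure D1:**
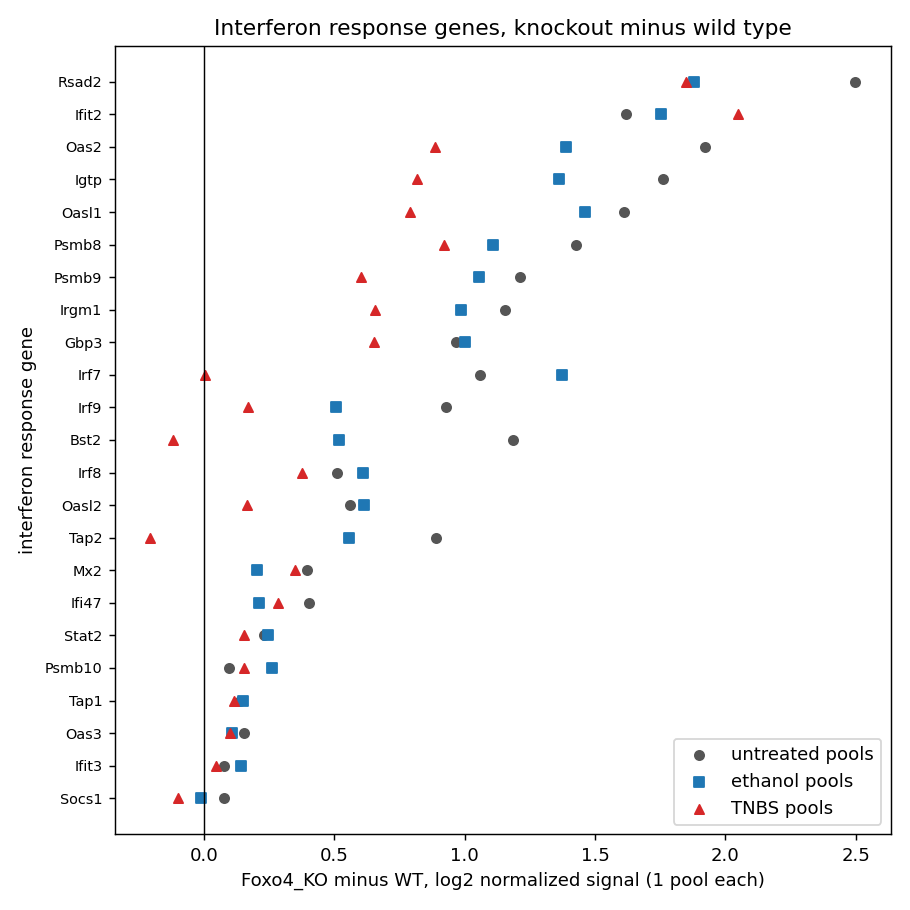
Foxo4_KO minus WT difference (log2, x axis) of the 23 measured interferon response genes (y axis), with 1 point for each of the untreated, ethanol and TNBS pairs of pools. Rsad2 stood at 2.50, 1.88 and 1.85 in these pairs.

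Of 35 tested gene lists, 16 passed camera with its preset correlation for genotype, 13 higher and 3 lower in Foxo4_KO. None passed with an estimated correlation or with fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. With an estimated correlation, a list shifted by 1 (log2) was called in 0 of 20 simulated data sets. An absent call with it, here and below, therefore says little. The interferon response list had an adjusted p of 6.01e-20 (adjusted p = 0.595 with an estimated correlation), with 15 of its genes higher when adjusted over the list alone and 0 over all genes. MHC class II presentation had 5.74e-06 (adjusted p = 0.595 with an estimated correlation), with 4 genes adjusted over the list alone and 0 over all genes. Chemokines (median 0.16, 13 of 21 higher in every pair) had 2.88e-05 (adjusted p = 0.595 with an estimated correlation), with 2 genes adjusted over the list alone and 0 over all genes. Their largest values were those of Ccl4 (1.16, SE 0.811), which came from the TNBS pools and was 0.09 without either of them, and Cxcl12 (0.72, SE 0.364). In the untreated pair Cxcl12 went the other way, at 8.44 in Foxo4_KO and 8.66 in WT. Targets of NF-kB, the transcription factor of many inflammatory genes, had a small median of 0.06 and 0.0136 (adjusted p = 0.634 with an estimated correlation), with no gene adjusted over the list alone or over all genes. Icam1 (0.32) and Vcam1 (0.35), which bind leukocytes to vessel walls, were among its largest values, and the list's call was lost without either TNBS pool (adjusted p = 0.349). Matrix remodelling genes had a median of 0.21 and 2.7e-07 (adjusted p = 0.595 with an estimated correlation), with 8 of 24 higher in every pair, 1 gene adjusted over the list alone and 0 over all genes. Their median was −0.02 in untreated, 0.45 in ethanol and 0.44 in TNBS pools, with high values of the basement membrane collagen Col4a1 (1.13, SE 0.469) and the gelatinase Mmp2 (0.86, SE 0.267).

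Markers of several cell types moved with genotype. Monocyte and macrophage markers were higher in every pair for 13 of 15 genes (median 0.14, adjusted p = 5.74e-06, and adjusted p = 0.595 with an estimated correlation). T and NK cell markers were higher in every pair for 6 of 8 (median 0.15, adjusted p = 8.18e-05), with 2 genes adjusted over the list alone, and B and plasma cell markers for 7 of 9 (median 0.23, adjusted p = 2.88e-05), with none. Both had an adjusted p = 0.595 with an estimated correlation. Dendritic cell markers had a median of 0.09, which turned to −0.03 under median scaling, 0.06 above the median gene, and an adjusted p of 0.0114 (adjusted p = 0.595 with an estimated correlation). Neutrophil markers had a median of 0.09 and 0.0046 (adjusted p = 0.637 with an estimated correlation). Their largest values, S100a9 (1.17, SE 0.942) and S100a8 (0.94, SE 1.03), came from the TNBS pools, since without either TNBS pool they were −0.07 and −0.40 and the list's adjusted p was 0.925. Smooth muscle genes had the largest median of these lists, 0.89 (adjusted p = 5.11e-05, and adjusted p = 0.595 with an estimated correlation), with Actg2 at 1.61 (SE 0.642) and 6 of 12 higher in every pair, and fibroblast and stroma genes had 0.23 (8 of 20, adjusted p = 2.88e-05, and adjusted p = 0.595 with an estimated correlation). Endothelium genes had 0.16 (4 of 12, adjusted p = 0.00017, and adjusted p = 0.595 with an estimated correlation). The untreated pair hardly took part in these values, with medians of 0.03, 0.01 and −0.02 for smooth muscle, fibroblast and stroma, and endothelium genes. The epithelium list had 0.00, or −0.04 under median scaling, 0.05 above the median gene, and was not called (adjusted p = 0.552).

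Lists lower in Foxo4_KO concerned metabolism and the clock. Xenobiotic metabolism had a median of −0.12 (adjusted p = 0.0458, and adjusted p = 0.595 with an estimated correlation), with Adh1, an alcohol dehydrogenase, at −1.03 (SE 0.239) and Cyp2d10 at −0.92 (SE 0.19). Hypoxia and glycolysis genes had −0.09 (adjusted p = 0.0136, and adjusted p = 0.595 with an estimated correlation), and 1 of them was lower adjusted over the list alone and 0 over all genes. Pdk1, which holds back pyruvate oxidation, stood at −0.47 (SE 0.055) and Ankrd37 at −0.53 (SE 0.089). Circadian clock genes had −0.14 (adjusted p = 0.0114, and adjusted p = 0.595 with an estimated correlation), with Per2 at −0.41 and Clock at −0.39. Their calls were lost without either untreated pool, with adjusted p of 0.295 for hypoxia and glycolysis, 0.484 for the clock and 0.527 for xenobiotic metabolism. The FoxO target list was not called (median 0.00, adjusted p = 0.922), nor were tight and adherens junction genes, with a median of 0.01, a mean of −0.01 and an adjusted p of 0.941. Under median scaling these lists had −0.08 and −0.09, where the median gene itself had −0.08.

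In untreated mice the question was which mucosal transcripts differ before any injury. The interferon list's median was higher by 0.93 in the Foxo4_KO pool, above all 10000 random lists of like signal, and 10 of its 23 genes were at least 2-fold higher. Ifi27l2a, an interferon-inducible mitochondrial protein, was 13.2-fold higher, Apol9a 5.66-fold, Rsad2 5.65-fold, Irgm2 5.14-fold and Oas2 3.79-fold. Nenf was 5.94-fold higher, the chloride channel regulator Clca4b 7.44-fold, and Duoxa2, the partner of the epithelial oxidase Duox2, 4.63-fold. The sodium channel subunits Scnn1g (−1.88, log2) and Scnn1b (−1.32) and Fxyd4 (−1.78) were lower, as were the clock output gene Dbp (−1.35), haemoglobin Hba-a1 (−1.42) and Adh1 (−1.26). Circadian clock genes were lower as a group (median −0.34, below all random lists) and smooth muscle genes hardly differed (median 0.03).

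A total of 40 genes were at least 2-fold higher and 17 at least 2-fold lower in the untreated Foxo4_KO pool among 8078 detected genes. Cyp4b1-ps2 (−2.02), Casp14 (−1.72), the transaminase Kyat1 (−1.55) and Sycn (−1.30) made up the rest of the 10 lowest. The Paneth cell defensins Defa3 and Defa31 were at least 4.21-fold and at least 3.81-fold higher, and both were below background in the untreated WT pool. Of ileal genes, chosen after their values were seen, Fabp6 (8.09 against 6.71) and Anpep (7.94 against 6.82) were also higher in Foxo4_KO. Abcg5 (6.93 against 7.38) and Rbp2 (7.54 against 8.10) were lower. Small-intestinal tissue in the untreated Foxo4_KO pool was not tested. Xist, the transcript of the inactive X chromosome in female cells, was high in both untreated pools (9.68 in WT and 10.25 in Foxo4_KO) and between 6.61 and 7.24 in the other 4 pools. Median scaling moved the median gene of this comparison by 0.11.

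In ethanol-treated mice the comparison asked how the genotypes differ under the vehicle. Interferon genes were again higher in the Foxo4_KO pool (median 0.61, 8 of 23 at least 2-fold), with Ifi27l2a 10.3-fold and Nenf 7.46-fold higher. The antigen presentation genes Cd74 and H2-Ab1 were 4.83-fold and 4.69-fold higher and the lysozyme Lyz2 of macrophages 4.62-fold. Smooth muscle genes of the contractile apparatus had the largest median of any list, 1.51, with Actg2 9.47-fold, Myh11 7.76-fold, Acta2 5.29-fold, Synm 4.98-fold and Tpm2 4.94-fold higher, and fibroblast and stroma genes moved with them (0.46). Among the 10 lowest genes were Fxyd4 (−3.28), Scnn1g (−2.03), Scnn1b (−1.96) and the proton pump Atp12a (−1.63), while the list of ion and solute transport genes had a median of −0.11, with 11 of 27 higher and 3 at least 2-fold lower.

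In all, 96 genes were at least 2-fold higher and 27 at least 2-fold lower in the ethanol-treated Foxo4_KO pool among 8001 detected genes. Antimicrobial and acute phase genes were lower as a group (median −0.20, below all random lists), including the lectin Reg3b (−1.44). Lrg1 (−1.43), Clca4b (−1.66), Arl2bp (−1.39) and Casp14 (−1.27) were also among the 10 lowest. Fbxw5 was at least 6.17-fold lower, and its probe was above background in the ethanol-treated WT pool and not in the ethanol-treated Foxo4_KO pool.

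In TNBS-treated mice the comparison asked how the injured mucosa differs without Foxo4. It rests on the Foxo4_KO TNBS array, which stood apart from all others, with correlations of 0.961 to 0.979 where every other pair of arrays had 0.981 to 0.991. Single genes of neutrophils and acute inflammation were far higher in the Foxo4_KO pool: S100a9 12.7-fold and S100a8 12.2-fold, the subunits of calprotectin, the cytokine Il1b 10.3-fold, the chemokine Ccl4 9.88-fold, the acute phase protein Saa3 4.93-fold and the siderophore-binding Lcn2 at least 4.67-fold. Antimicrobial and acute phase genes had a median of 0.64 with 8 of 23 at least 2-fold higher, and chemokines had a median of 0.21. The antimicrobial list holds Lyz1 and Pla2g2a, also Paneth cell genes, which read 10.03 and 11.94 in Foxo4_KO and 7.48 and 10.64 in WT. It was not tested without such genes. Whether the 2 TNBS pools held unequal small-intestinal tissue was not tested. At least 2-fold higher were 4 of 14 neutrophil genes, 1 of 11 inflammatory cytokines and 1 of 21 NF-kB targets. The neutrophil list's median was 0.27, which turned to −0.08 under median scaling, where the median gene itself moved by −0.28 and the list stood 0.22 above it. Aqp8, the water channel of the colonocyte surface, was lower (−1.64), as were the hormone Insl5 (−1.56), the phosphate transporter Slc20a1 (−1.48), the carbonyl reductase Cbr2 (−1.77) and Fxyd4 (−1.51).

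These differences came from 106 genes at least 2-fold higher and 49 at least 2-fold lower among 8638 detected genes. Among the 10 highest were also the Paneth cell genes Defa31 (7.93-fold), Lyz1 (5.89-fold) and Defa24 (5.16-fold). Smooth muscle genes had a median of 0.74, with Csrp1 at least 4.64-fold higher, and matrix remodelling genes 0.44. Interferon genes had a median of 0.29, the smallest of the 3 pairs of pools. Prmt1 (−1.65), Mtch2 (−1.62), Btg1 (−1.61), Eno3 (−1.60) and Ly6g6c (−1.57) made up the rest of the 10 lowest. A second probe of Mtch2 read 8.98 in the WT and 8.84 in the Foxo4_KO pool. Those of Btg1 and Fxyd4 read 8.86 and 8.09 in WT and 7.49 and 7.1 in Foxo4_KO. The dimmer probes of Acaa2, chosen after its values were seen, read 8.32 and 8.77 in WT and 7.67 and 7.69 in Foxo4_KO. Its brightest read 11.73 and 12.02. With every probe kept apart, 116 probes were at least 2-fold higher and 66 lower. Why probes of the same gene differed was not tested.

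**Figure D2:**
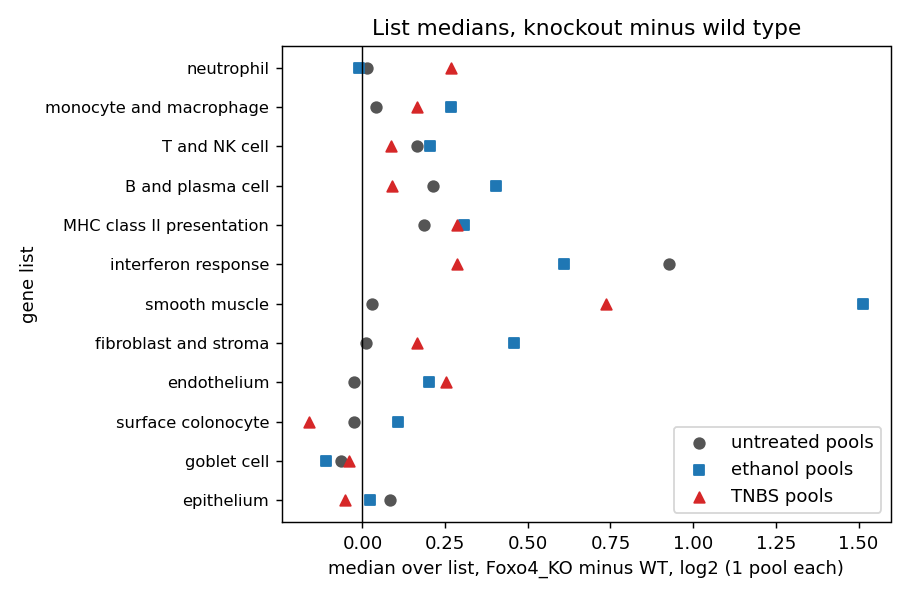
Median Foxo4_KO minus WT difference (log2) of 12 gene lists in the untreated, ethanol and TNBS pairs of pools. The interferon list stood at 0.93, 0.61 and 0.29, the smooth muscle list at 0.03, 1.51 and 0.74, and the neutrophil list at 0.01, −0.01 and 0.27, the last of which turned to −0.08 under median scaling.

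The response to TNBS was then compared between genotypes, as the TNBS minus ethanol difference in Foxo4_KO pools minus that in WT pools. S100a8 (4.44), S100a9 (3.79), Il1b (3.50), Ccl4 (3.28), Lrg1 (3.07) and Lcn2 (2.47) had larger values of TNBS minus ethanol in Foxo4_KO. Antimicrobial and acute phase genes as a group had a median difference of 0.98, with 11 of 23 at least 2-fold higher. This list, which includes Paneth cell genes, was not tested without them for this difference. Between TNBS and ethanol the median neutrophil gene differed by 0.02 in the WT and 0.37 in the Foxo4_KO pools, but the size of this contrast depended on scaling: under median scaling the values were −0.03 and 0.01, the latter 0.27 above the median gene, and with the authors' values the Foxo4_KO median was 1.08. The Paneth cell genes Defa31 (2.45), Lyz1 (2.36) and Defa24 (2.25) were also among the highest, as was the pancreatic-type amylase Amy2a5 (2.31). Lower differences of responses were those of Aqp8 (−2.49), Slc20a1 (−2.36), Ly6g6c (−3.02) and the desaturase Scd1 (−1.90).

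In this difference of responses 88 genes were at least 2-fold higher and 95 at least 2-fold lower among 8807 detected genes. With every probe kept apart, 93 probes were higher and 132 lower by this measure. S100a8, S100a9 and Il1b were below background in the ethanol-treated Foxo4_KO pool, and S100a8 read 7.34 in the ethanol-treated WT pool. S100a9, Defa31, Lyz1 and Defa24 were below background in the ethanol-treated WT pool, as Amy2a5 and Lcn2 were in the WT TNBS and Foxo4_KO ethanol pools, so their differences of responses rest in part on background values. Smooth muscle genes had a median of −1.04, with Actg2 at −2.05, and skeletal-type Acta1 stood at −3.16. Ifi27l2a stood at −3.01, Cpn1 at −2.12, Mtch2 at −2.01 and Hao2 at −1.98. Median scaling moved the median gene by −0.25 here, and no difference of responses could be tested with 1 pool per group.

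The vehicle itself was compared with no treatment over both genotypes. Pla2g2a, a secreted phospholipase of Paneth cells and inflamed gut, was higher by 2.01 (SE 0.46), Ly6d by 1.54 (SE 0.16), Gsta3, a glutathione transferase, by 1.44 (SE 0.168) and the endothelial Ly6c1 by 1.37 (SE 0.179). Lower values were those of endothelin Edn1, at −1.10 (SE 0.291), and Xist, at −3.34 (SE 0.193). Xist was high in both untreated pools and low in all pools given an enema. Any difference in sex between these pools would therefore coincide with ethanol minus untreated and with TNBS minus untreated. Among the enema pools Xist was highest in the Foxo4_KO TNBS pool, at 7.24 against 6.61 in the WT TNBS pool. A difference in sex could therefore also enter Foxo4_KO minus WT under TNBS and the difference of responses, which was not tested. Mcm4 of DNA replication stood at 0.56 (SE 0.114) and Birc5 of cell division at 0.53 (SE 0.175), and of surface colonocyte genes the brush border protease Mep1a stood at −0.86 (SE 0.135) and the carbonic anhydrase Car4 at −0.49 (SE 0.159). The genes named by their 2-fold difference in both pairs, 4 higher and 2 lower, were chosen after their values were seen.

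No gene passed in limma for ethanol against untreated, where the lowest adjusted p was 0.725, with 248 genes higher and 265 lower at an unadjusted p under 0.05, and the trended and robust prior called 1 gene, Xist. By camera 9 lists passed, 6 higher and 3 lower, none with an estimated correlation or with fry, and none kept its call without each array in turn. Cell cycle genes had a median of 0.27 (adjusted p = 2.88e-05, and adjusted p = 0.796 with an estimated correlation), with 0.26 in WT and 0.03 in Foxo4_KO pools and 14 of 28 higher in both. Antimicrobial and acute phase genes had 0.16 (adjusted p = 0.00941, and adjusted p = 0.805 with an estimated correlation), with 0.31 in WT and 0.03 in Foxo4_KO. Smooth muscle genes had 0.53 (adjusted p = 0.00199, and adjusted p = 0.796 with an estimated correlation), made up of 0.03 in the WT and 1.38 in the Foxo4_KO pools. Enteroendocrine genes had 0.08 (adjusted p = 0.00941, and adjusted p = 0.796 with an estimated correlation), with the hormones Insl5 at 0.94, Gcg at 0.69 and Pyy at 0.61. Matrix remodelling had 0.08 (adjusted p = 0.0117, and adjusted p = 0.85 with an estimated correlation), but −0.03 in WT and 0.36 in Foxo4_KO, with the membrane protease Mmp14 at 0.40 as its 1 gene adjusted over the list alone. Housekeeping genes had 0.10 (adjusted p = 0.0117, and adjusted p = 0.796 with an estimated correlation). They were included as a control list, so list medians of that size in this contrast need not be specific to a pathway or cell type. Surface colonocyte genes had −0.25 (adjusted p = 0.00289, and adjusted p = 0.796 with an estimated correlation), −0.37 in WT and −0.07 in Foxo4_KO. Fatty acid oxidation and TCA cycle genes had −0.06 (adjusted p = 0.0359, and adjusted p = 0.796 with an estimated correlation), with −0.13 in WT, 0.01 in Foxo4_KO and Hadhb at −0.44. A dimmer probe of Hadhb read 7.23 with ethanol against 7.30 untreated in WT, but 7.29 against 6.98 in Foxo4_KO. T and NK cell genes had −0.09 (adjusted p = 0.0359, and adjusted p = 0.805 with an estimated correlation), which turned to 0.15 under median scaling, where the list stood only 0.01 above the median gene.

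TNBS was compared with its vehicle over both genotypes. The Paneth cell defensin Defa20 was higher by 4.59 (log2, SE 0.0968, adjusted p = 0.0424 in limma). It read 10.98 against 6.55 in WT and 11.76 against 7.02 in Foxo4_KO, and it was below background in the ethanol-treated WT pool. Small-intestinal tissue in the TNBS pools is a candidate explanation, taken up under other observations. Of genes of the small intestine, Fabp6, the bile acid binding protein of the ileum, read 11.74 against 6.90 in WT and 12.15 against 7.40 in Foxo4_KO, and the aminopeptidase Anpep read 10.32 against 7.28 and 11.59 against 7.72. Haptoglobin Hp was higher by 2.50 (SE 0.475), the bactericidal lectin Reg3g by 2.22 (SE 0.39), S100a8 by 2.46 (SE 1.26) and S100a9 by 2.07 (SE 1.15). The values of S100a8 and S100a9 came from the Foxo4_KO TNBS pool, since without it they were 0.46 and 0.20, and both were below background in the Foxo4_KO ethanol pool, as was S100a9 in the WT ethanol pool. Adipoq, the hormone of fat cells, was higher by 1.79 (SE 0.063, adjusted p = 0.0825). Fabp6 and Anpep were chosen here after their values were seen.

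Besides Defa20, no gene passed in limma for TNBS against ethanol, and 291 genes were higher and 259 lower at an unadjusted p under 0.05, while 26 genes were at least 2-fold higher in both genotypes and none 2-fold lower. Defa20 lost its call when any 1 array was left out, and the trended and robust prior called 10 genes. By camera 7 lists passed, all with an adjusted p = 0.882 with an estimated correlation and none with fry, and of these the antimicrobial list alone was called without each array in turn. Antimicrobial and acute phase genes had a median of 0.45 (adjusted p = 1.07e-05), with 17 of 23 higher in both genotypes. This list holds Lyz1 and Pla2g2a, which are also Paneth cell genes. It was not tested again without small-intestinal and Paneth cell genes. Neutrophil genes had 0.19 (adjusted p = 0.000339), with 12 of 14 higher in both, but the median was 0.00 under median scaling (0.14 above the median gene) and 0.57 with the authors' values, and the call was lost without the Foxo4_KO TNBS pool (adjusted p = 0.188). Matrix remodelling had 0.11 (adjusted p = 0.0231), with the protease inhibitor Timp1 at 0.70, and goblet cell genes 0.12 (adjusted p = 0.0173), with the mucin-folding Agr2 at 0.27 and Muc4 at −0.28. Adipocyte genes had 0.12, which turned to −0.12 under median scaling, 0.01 above the median gene (adjusted p = 0.0122), with 1 gene, Adipoq, adjusted over the list alone and 0 over all genes. Xenobiotic metabolism had −0.21 (adjusted p = 0.0404), although Cyp2e1, an enzyme of liver and fat, was higher by 1.78 (adjusted p = 0.131) where Ugt1a6a was at −1.17 (−0.77 without the Foxo4_KO TNBS pool). Fatty acid oxidation and TCA cycle genes had −0.07 (adjusted p = 0.0122), with Acadm at −0.60 and Suclg1 at −0.72 (−0.25 without the Foxo4_KO TNBS pool). The inflammatory cytokine list was not called (adjusted p = 0.0519).

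**Figure D3:**
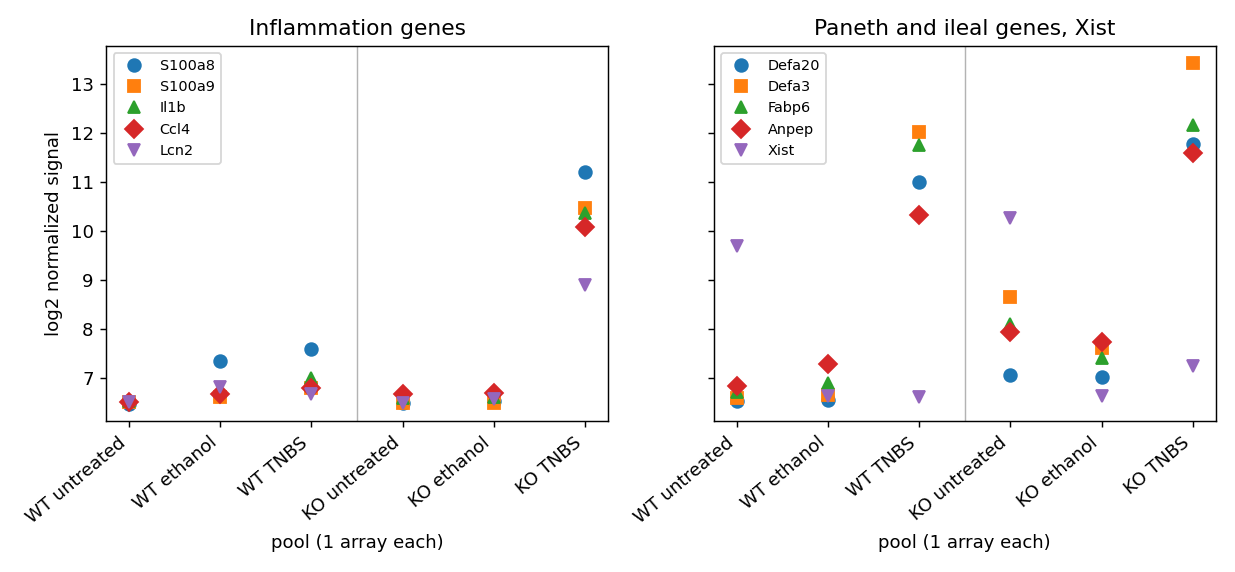
Normalized log2 signal of 10 genes in the 6 pools, with inflammatory genes in one panel and Defa20, Defa3, Fabp6, Anpep and Xist in the other. S100a8 reached 11.20 in the Foxo4_KO TNBS pool and 7.58 in the WT TNBS pool, whereas Defa20 read 11.76 and 10.98 in these pools.

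Against untreated mucosa, TNBS pools combined vehicle and hapten, and any difference in sex that the Xist values may reflect. Defa20, below background in the untreated WT pool, was higher by 4.58 (SE 0.0968, adjusted p = 0.0426 in limma). It was again the only gene past the threshold, with 576 genes higher and 495 lower at an unadjusted p under 0.05. Among antimicrobial and acute phase genes Pla2g2a was higher by 3.91 (SE 0.46, adjusted p = 0.306) and Hp by 2.70 (SE 0.475). Contractile Actg2 was higher by 3.33 (SE 0.786) and Vim of mesenchymal cells by 1.14 (SE 0.419). Of the unfolded protein response list Asns stood at 1.11, Creld2 at 0.74 and Pdia3 at 0.66, with 13 of 23 genes higher and 4 lower in both genotypes, and the colonocyte channel Aqp8 stood at −1.71 (SE 0.686), or −0.65 without the Foxo4_KO TNBS pool.

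By camera 16 lists passed for TNBS against untreated, 10 higher and 6 lower, with an adjusted p = 0.532 with an estimated correlation for each except fibroblast and stroma (adjusted p = 0.548). Higher were antimicrobial and acute phase genes (median 0.65, adjusted p = 6.32e-08, 4 genes adjusted over the list alone and 0 over all genes), cell cycle genes (0.18, adjusted p = 1.16e-06, 24 of 28 higher in both genotypes), matrix remodelling (0.26, adjusted p = 0.000156) and neutrophil genes (0.24, adjusted p = 0.000857). Smooth muscle genes (0.76, adjusted p = 0.00517), enteroendocrine genes (0.14, adjusted p = 0.00943), the unfolded protein response (0.08, adjusted p = 0.0177), fibroblast and stroma (0.15, adjusted p = 0.0183), chemokines (0.08, adjusted p = 0.0317) and housekeeping genes (0.13, adjusted p = 0.046) were also higher. Lower were fatty acid oxidation and TCA cycle genes (−0.21, adjusted p = 3.29e-05, 21 of 33 lower in both genotypes), surface colonocyte genes (−0.38, adjusted p = 0.00943) and xenobiotic metabolism (−0.33, adjusted p = 0.0282), as were B and plasma cell (−0.16, adjusted p = 0.0183), T and NK cell (−0.10, adjusted p = 0.0282) and MHC class II genes (−0.11, adjusted p = 0.0317). Within the surface colonocyte list Anpep went the other way, at 3.57 (adjusted p = 0.222). Fry called 4 lists, all higher. They were housekeeping genes (adjusted p = 0.0125), NRF2 and oxidative stress (adjusted p = 0.0296), adipocyte genes (adjusted p = 0.0302) and enteric neuron and glia (adjusted p = 0.0416). Camera did not call the last 3 of these. Housekeeping genes were the control list, and both tests called it here, so small medians of other lists need not be specific to a pathway. The antimicrobial, cell cycle and fatty acid oxidation lists kept their calls without each array in turn, and the others lost theirs in at least 1 case, most often without the untreated Foxo4_KO pool. The antimicrobial list was not tested here either without small-intestinal and Paneth cell genes.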

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

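No test was run on the values of this part, and all of them were picked out by fixed rules applied after the values were computed. Acta1, a striated muscle actin, differed in its TNBS minus ethanol value by −3.16 (Foxo4_KO minus WT, log2), since it was higher with TNBS in the WT pools (1.16) and lower in the Foxo4_KO pools (−2.00), a difference between groups that was not tested. Ifi27l2a, an interferon-inducible gene, differed in the same way by −3.01, with 1.14 in WT and −1.87 in Foxo4_KO, which was not tested either. Among 16633 joined probes with no gene symbol, which the comparisons left out, 2063 were above background on all 6 arrays, where the detection threshold alone would give 1.66e-08 if the arrays were independent.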

How the results depend on the processing

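Tests without both TNBS or both untreated pools and without small-intestinal genes were chosen after the results were seen; the other settings were not. Among called lists, 10 of 16 for genotype were called without each array in turn, 0 of 9 for ethanol minus untreated, 1 of 7 for TNBS minus ethanol and 3 of 16 for TNBS minus untreated. The dendritic cell list lost its genotype call without any 1 of the ethanol or untreated arrays, the neutrophil and NF-kB lists without either TNBS array, the hypoxia and clock lists without either untreated array, and the xenobiotic list without any 1 of the TNBS or untreated arrays. Without both TNBS pools 13 lists were called for genotype, as without both untreated pools. Counts of genes at least 2-fold apart ranged over all settings from 47 to 66 in untreated, 101 to 184 in ethanol and 126 to 182 in TNBS pools, and from 146 to 225 for the difference of responses. Signal over background limits these values: the lowest detected log2 signal was 6.56 to 6.58, and genes near it have compressed differences. The cause was not tested for any change below unless stated.

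With no background correction, 13 genes passed for genotype (all higher), 16 for TNBS minus ethanol and 30 for TNBS minus untreated, with 14 lists for ethanol minus untreated and 11 for TNBS minus ethanol, and the authors' values gave the same counts of 13, 16, 30, 14 and 11. In WT pools ethanol minus untreated then had 26 genes higher and 16 lower (27 and 16 with the authors' values) against 23 and 24, and in Foxo4_KO pools 64 and 6 against 48 and 13. An offset of 50, no detection filter and every probe kept apart each gave 0 genes for TNBS minus ethanol and 0 for TNBS minus untreated. Median scaling gave 169 genes for genotype, 36 for ethanol minus untreated, 93 for TNBS minus ethanol and 225 for TNBS minus untreated, with an infinite prior df and a prior SD of 0.23. It reversed Ccr7 for genotype (−0.023) and Thrsp (−0.049) and Plin1 (−0.08) for TNBS minus ethanol, and moved the median gene by 0.11 in untreated, −0.28 in TNBS pools, −0.25 in the difference of responses, 0.18 for ethanol in WT and −0.25 for TNBS in Foxo4_KO. A trended and robust prior gave 4, 1, 10 and 17 genes in that order of contrasts. Leaving the covariate out gave 5 genes for genotype (Dlk1, Lgals9, Parp9, Rsad2 and, lower, Pdzk1ip1) and 2 for each TNBS contrast (Adipoq and Cyp2e1). An estimated correlation gave 0 lists in each of the 4 contrasts, and fry gave 0, 0, 0 and 4. Detection on all 6 arrays called 1 gene for each TNBS contrast, Lgals2 in place of Defa20, whose probe that filter removes. Without small-intestinal genes, Defa20 among them, TNBS minus ethanol had 0 genes, and 27 in place of 41 genes were at least 2-fold apart in WT pools.

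Without 1 array at a time, both TNBS contrasts ranged from 0 to 0 genes, the lists for ethanol minus untreated from 3 (without the untreated Foxo4_KO array) to 10 and those for TNBS minus untreated from 4 (without the same array) to 14, being 10 without the Foxo4_KO TNBS array. Without the Foxo4_KO TNBS array 9 of 21 single genes recomputed for TNBS minus ethanol and 16 of 48 for TNBS minus untreated kept less than 0.5 of their value or reversed. For genotype, Ier3 ranged from −0.054 to 0.60, S100a9 from −0.075 to 1.82 and S100a8 from −0.40 to 1.82, each lowest without either TNBS array, and Dbp from −0.76 to 0.17, highest without either untreated array. For ethanol minus untreated, Reg3b ranged from −0.70 to 1.73 and Cdca3 from −0.003 to 0.86, both lowest without the WT ethanol array, and Col4a1 from −0.47 to 1.36, lowest without the untreated Foxo4_KO array. The matrix remodelling list's adjusted p there ranged from 3.9e-10 to 0.627, and its direction reversed at the latter value, without the Foxo4_KO ethanol array. For TNBS minus ethanol, Thrsp ranged from −0.089 to 0.63 (lowest without the WT TNBS array), Tgfbi from −0.12 to 1.45 (lowest without the Foxo4_KO TNBS array) and Muc4 from −0.585 to 0.027 (highest without the Foxo4_KO TNBS array). For TNBS minus untreated, Mzb1 ranged from −0.86 to 0.027 (highest without the Foxo4_KO TNBS array) and Dcn from −0.11 to 1.51 (lowest without the untreated Foxo4_KO array).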

Other observations

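Among the tests below, those of small-intestinal tissue, of inflammation, of sex and of immune cells were chosen only after the result was seen. The genes of this paragraph were chosen after their values were seen. Against ethanol the haemoglobin genes Hba-a1 and Hbb-bs were higher by 1.63 and 1.65, the fat and muscle carbonic anhydrase Car3 by 1.86 (SE 0.329) and the basal keratin Krt14 by 1.37 (SE 0.185). Against untreated mucosa Socs3, which restrains cytokine signalling, was higher by 2.02 (SE 0.529), the lectin Lgals1 by 2.02 (SE 0.351), the gut glutathione peroxidase Gpx2 by 1.65 (SE 0.457) and the chaperone Clu by 1.30 (SE 0.204). The clock repressor Nr1d1 stood at −1.49 (SE 0.145) and the antiproliferative Btg1 at −1.38 (SE 0.439). None of these passed the adjusted threshold.

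Within a genotype, TNBS pools differed from ethanol pools at least 2-fold in 38 genes higher and 3 lower in WT (Rbm3, Scnn1g and Tlr2, chosen after their values were seen) and in 102 higher and 76 lower in Foxo4_KO. With every probe kept apart, the counts of probes were 45 and 3 in WT and 116 and 115 in Foxo4_KO. Ethanol pools differed from untreated pools in 23 genes higher and 24 lower in WT and in 48 higher and 13 lower in Foxo4_KO. In Foxo4_KO, TNBS minus ethanol had medians of 0.80 for antimicrobial and acute phase genes, −0.30 for B and plasma cell genes and −0.31 for xenobiotic metabolism. The same lists had 0.17, 0.03 and −0.08 in WT. The antimicrobial list includes Paneth cell genes here too.

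Interferon response genes were higher in the Foxo4_KO pool of every treatment. For the genotype effect over all treatments, array scaling was argued against as the whole cause. The list's lowest median over 5 scalings, all but 1 of them quantile normalized, was 0.44, where the largest shift of the median gene was −0.084. In the TNBS pair the list's median was 0.29, and median scaling moved the median gene by −0.28, so scaling stays open for that pair. More immune cells in the Foxo4_KO pools and no such difference cannot be told apart: 8 leukocyte markers of at least median brightness had a median genotype effect of 0.934 (quartiles 0.133 and 0.963) against the interferon list's 0.53 (quartiles 0.255 and 1.05), but the pairs of pools ranked them differently, with 0.34 against 0.93 in untreated, 0.90 against 0.61 in ethanol and 0.37 against 0.29 in TNBS pools. The whole lists, with their dimmer markers, had medians of only 0.14 for monocytes, 0.15 for T and NK cells, 0.23 for B and plasma cells and 0.09 for dendritic cells. Loss of Foxo4 itself, and other differences between the mouse lines, stay open and were not tested. The 10 splits of the 6 arrays into 3 against 3 cannot give a share under 0.05. For gene lists the real split gave 16, the others from 4 to 12, and 1 of 10 splits as many. For genes the real split gave 0, the highest other 0, and 10 of 10 as many. The 9 lists called for ethanol minus untreated and the 7 for TNBS minus ethanol lie within the range of the other splits. Counts of that size therefore also arose by camera from groupings that mix genotypes.

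A group of 9 small-intestinal and Paneth cell genes, chosen after their values were seen, was high in both TNBS pools. A candidate explanation is small-intestinal tissue in the TNBS pools: a further list of ileal enterocyte genes, written before this test, had medians of 0.17 in WT and 0.33 in Foxo4_KO (TNBS minus ethanol), both at percentile 100 of random lists, with 20 and 19 of 22 measured genes higher, 1 and 4 of them at least 2-fold. Of these 22 genes 15 were detected in untreated WT colon and 1 was in another list, and the abundant Apoa1 read 10.55 against 8.85 in WT and 11.80 against 8.54 in Foxo4_KO, while a further 8 of the 30 genes on the array, among them Fabp2 and Slc10a2 of ileal enterocytes, were not above background on any array. Over the 13 genes detected in both untreated pools, a filter that no TNBS array enters, the medians were 0.21 and 0.66 (percentiles 99.99 and 100), while the only 3 so detected genes of a like Paneth cell list had 0.07 and 0.38 (percentiles 76.2 and 94.8). Under the main filter, which TNBS arrays enter, the 7 measured genes of that Paneth list had 0.985 in WT and 2.72 in Foxo4_KO. Both were at percentile 100, with 6 and 7 genes higher. Induction in step with inflammation and its absence cannot be told apart. The median difference of responses over the 9 genes was 0.396. An interval from resampling these chosen genes, −0.09 to 0.75, holds 0, and it measures spread between genes, not between pools. The median response of the 9 genes was 3.04 in WT and 3.36 in Foxo4_KO. There the neutrophil medians were 0.02 and 0.37, or −0.03 and 0.01 under median scaling.

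Xist was high in both untreated pools and low in the other 4. By the other X-linked and the Y-linked genes given below, pools of different sex and pools of the same sex cannot be told apart. X-linked genes that escape inactivation were higher in the untreated than in the ethanol pools by a mean of 0.507 and than in the WT TNBS pool by 0.50, but in Foxo4_KO their mean untreated minus TNBS difference was −0.07, with Kdm6a at 0.22, Kdm5c at 0.23, Eif2s3x at −0.31 and Ddx3x at −0.40, although Xist read 7.24 in that TNBS pool. Of the Y-linked genes Eif2s3y and Uty were not above background on any array, and Kdm5d was on 1, reading 6.57, 6.58, 6.60 and 6.62 in the pools with low Xist and 6.45 and 6.46 in the untreated pools, all near the floor. A sample taken from another source was not tested.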
